A study of Rattus norvegicus with 15 samples.

How the data were processed

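Liver RNA from male Fischer344 rats (given as Fischer for 1 control sample) was measured on 15 arrays, 5 from control liver, 5 from noncancerous cirrhotic liver and 5 from hepatocellular carcinoma. Groups and replicate numbers were taken from the sample titles. The labels describe each sample as coming from a male rat and do not say whether samples with the same number share an animal, nor that the samples of a group are separate animals, so the p-values measure the spread between these samples. The deposited values are a linear ratio: in all 3757 probes the median over the 15 arrays was 1 within a tolerance of 1e-06, so each probe had been divided by its own median before deposit. The deposited array medians lay between 0.919 and 1.02, and no deposited ratio was under 0.01, a limit reached by 657 values in 555 probes. The array type, dyes, scanner, background correction and software are not given in the sources used here. The table holds no absolute level and no detection call. Dividing by a probe median keeps differences between samples on the log2 scale and removes any ranking of genes by brightness. Every column of the table was used, and 0 columns were left aside.

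Of the 3757 probes, 3440 had 1 gene symbol in the platform annotation and together covered 3400 genes, 4 had several symbols, and 313 had none listed. A symbol was checked through its gene identifier in a table of RefSeq genes of the assembly GRCr8, where 3429 of the 3440 matched. No coordinates are given, because the arrays name no genome build. Probes with several symbols or none were tested and not named.

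The fit, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The highest array mean, trimmed by 2% at each end, was 1.49 times the lowest, above the ratio of 1.2 fixed as the limit for using the values as they stood, so the ratios were quantile-normalized over the 15 arrays and then put on the log2 scale. The filter on dim probes kept all 3757 probes, because on ratios to the probe's own median a low ratio is no sign of a dim probe. It therefore had no effect. The plan had been written for brightness values, and 2 steps were changed once the unit was known. The planned floor at the 10th percentile (a ratio of 0.363) was not applied, because it would have removed real low ratios. It was run as an alternative. Where a gene had more than 1 probe, as 38 genes did, the probe with the smallest spread within groups was used, because the planned highest mean has no meaning on centred ratios. These changes were settled after several settings had been run, none of which gave a probe past the adjusted threshold.

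All 15 samples entered 1 linear model with group as the only term (12 residual degrees of freedom), fitted with lmFit and eBayes with a mean-variance trend in limma 3.58.1 under R 4.3.3. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 3757 probes of each comparison, with a threshold of 0.05. Differences are on the log2 scale of the normalized ratios, with 95% intervals from the moderated standard error. Complete separation means that all 5 values of a group lay beyond all 5 of the other, which chance gives for 0.794% of probes. The 29 fixed gene lists of pathways and cell type markers were tested with camera at a preset correlation of 0.01, adjusted over 84 tests (28 lists with at least 5 measured genes, 3 comparisons), and again with an estimated correlation, with fry, and with an exact permutation test of the list mean per sample over 252 splits, two-sided, whose smallest possible p is 0.00794. Spread within a group was compared by the same exact permutation test. Figures were drawn with matplotlib 3.10.9.

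The fixed rule named genes past the adjusted threshold, and 16 marker genes always, of which 14 were measured here. No probe passed the threshold. The other genes in the text were therefore chosen after their values were seen: per comparison the 8 genes most above and the 8 most below among those with complete separation, and 5 members of each list past the camera threshold.

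The fit was tested on simulated data for the comparison of hepatocellular carcinoma with control liver, with the 3757 probes, 200 of them changed, in 20 draws that dealt the residuals of whole arrays to the samples. It recovered 3% of probes changed 2-fold, 31.6% of those changed 4-fold, 75.4% of those changed 8-fold and 95% of those changed 16-fold, with 4.3 false calls per draw. The list test recovered a list of 40 random genes moved by 0.5 on the log2 scale in 12 of 20 draws, and one moved by 1 in 20 of 20.

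Alternatives were the values as deposited, scaling each array to the same median, a pseudocount, a floor at the 25th percentile, a stricter filter, no mean-variance trend, only the 2 groups compared, array quality weights, the mean of a gene's probes, the replicate number as a block, and leaving out each sample in turn. Added after seeing the data were the removal from each array of a running median along the probe numbering, with 3 window widths and with array quality weights, the 10th percentile floor, values at the lower limit set to missing, leaving out control 1 and noncancerous 1 together, and the exact permutation test of the lists.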

Results

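Transcripts were measured in liver tissue of male Fischer344 rats (given as Fischer for 1 control sample) after 70 weeks on a diet. Control liver came from 5 samples of rats on a basal diet. The other 10 samples came from rats on a choline-deficient, amino acid-defined diet, which leads to fatty change, cirrhosis and liver tumours in rats. Of these, 5 were hepatocellular carcinomas and 5 were the cirrhotic, noncancerous liver around such tumours. Each sample gave a ratio for 3757 probes, in which 1 is the probe's own median over the 15 arrays. Values at the lower limit of 0.01 numbered 229 in control 1 and 209 in noncancerous 1, 76 in control 3, 65 in control 2, 33 in carcinoma 1, and 0 to 10 in each of the other samples. The number of arrays limits the precision: the median half-width of the 95% interval of a difference was 1.27 on the log2 scale. The deposited ratios also shifted in long stretches of neighbouring probe numbers, and these shifts differed between samples.

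The first comparison set noncancerous cirrhotic liver against control liver, for the change that came with the diet and cirrhosis outside the tumour. Pemt, which makes phosphatidylcholine from phosphatidylethanolamine, was the 1 fixed marker whose values separated the groups completely. Its normalized log2 ratio was -0.69 ± 0.57 (SD, n = 5) in cirrhotic liver and 0.78 ± 0.54 (SD, n = 5) in control liver, a difference of -1.47 (95% interval -2.41 to -0.53, limma adjusted p = 0.315). With the running median along the probe numbering removed, the difference was -0.68 (-1.43 to 0.08) and the separation was lost. Col1a1, a chain of type I collagen, differed by -1.11 (-2.22 to -0.01, adjusted p = 0.511). Ccnd1, the cell cycle regulator cyclin D1, differed by 1.29 (-0.09 to 2.68), and Ggt1, an enzyme of preneoplastic liver foci in the rat, by 0.91 (-0.14 to 1.96). Gstp1, another enzyme of such foci, differed by 0.50 (-0.90 to 1.90), and none of these passed the test. The value of Ccnd1 rested on noncancerous 1, without which it was 0.77. That of Gstp1 ranged from 0.23 without noncancerous 4 to 0.86 without noncancerous 1.

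No probe passed an adjusted p of 0.05 in limma between noncancerous cirrhotic and control liver (smallest 0.307). At an unadjusted p under 0.05 there were 362 probes, 151 higher and 211 lower in cirrhotic liver, where 187.9 of 3757 come by chance. Complete separation was seen for 62 probes, 25 higher and 37 lower, against 29.8 by chance. These expectations hold for independent probes, and with the residuals of whole arrays dealt to unchanged groups, 14 of 100 simulated draws gave as many unadjusted probes (highest 992) and 11 as many separated ones (highest 329). Among genes with complete separation, chosen after their values were seen, the differences furthest above 0 belonged to Syn2 at 2.76 (1.63 without control 4), Acp2 (lysosomal acid phosphatase) at 2.73, Cd28 (a costimulatory receptor of T cells) at 2.57, Add2 at 2.44, Slc6a15 at 2.39, Slc9a3 (a sodium-proton exchanger) at 2.32, Ppt1 (a lysosomal thioesterase) at 2.29 and Cebpb (a liver transcription factor) at 1.98. Those furthest below 0 belonged to Apeh (8.02-fold lower), Pou3f3 at -2.42, Mgat5 (a glycosyltransferase of N-glycans) at -2.29, Stmn1 (a regulator of microtubules) at -2.22, Got1 (cytosolic aspartate aminotransferase) at -2.20, Mark1 at -2.03, Atic (an enzyme of purine synthesis, 4.01-fold lower) and Arid4b at -1.96.

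No gene list shifted between noncancerous cirrhotic and control liver by camera. Glycolysis genes of nonhepatic type had a median difference of 0.77 over 20 genes, 16 of them above 0 (camera adjusted p = 0.0657, and adjusted p = 0.684 with an estimated correlation). The growth hormone axis and sex-dependent liver genes had a median of 0.33 over 24 genes, with means per sample of 0.25 ± 0.21 in cirrhotic and -0.15 ± 0.05 in control liver (SD, n = 5 each; camera adjusted p = 0.155, adjusted p = 0.684 with an estimated correlation, and exact permutation p = 0.00794, adjusted 0.222). The cytochrome P450 genes had a median of 0.28 over 35 genes, 28 of them above 0 (adjusted p = 0.155). Extracellular matrix genes had a median of -0.13 over 39 genes (adjusted p = 0.539), stellate cell and myofibroblast markers 0.38 over 15 (adjusted p = 0.465), and preneoplastic focus and fetal liver markers 0.47 over 19 (adjusted p = 0.494). With adjustment over the list alone, 1 extracellular matrix gene, 1 stellate cell marker and 0 preneoplastic markers passed, and over all probes 0 did.

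Differences between noncancerous cirrhotic and control liver followed the probe numbering. Their median was 0.89 over probe numbers 1200 to 1399 and -1.07 over numbers 3600 to 3799, and with a running median along the numbering removed the unadjusted count was 158 in place of 362, with 85 higher in place of 151. Pemt then differed by -0.68, Col1a1 by -0.39, Ccnd1 by 0.92, Ggt1 by 0.12 and Gstp1 by 0.04, and 6 of the 16 separated genes above remained separated. Pemt, whose probe lies among numbers 3600 to 3799, was no longer separated. Cebpb moved to 1.06, Stmn1 to -1.06, Got1 to -1.05, Atic to -1.30 and Arid4b to -1.08. Glycolysis genes passed camera as higher in cirrhotic liver without noncancerous 2 (adjusted p = 0.00685), control 1 (0.00896), control 3 (0.0115), carcinoma 4 (0.0486) or carcinoma 3 (0.0497), and cytochrome P450 genes without control 3 (0.0325). Without control 1 and noncancerous 1 together, cytochrome P450 (0.0119), glycolysis (0.0493) and immediate early and heat shock genes (0.0493) passed, while with an estimated correlation the adjusted p in each of these settings was 0.648 or higher.

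**Figure D1:**
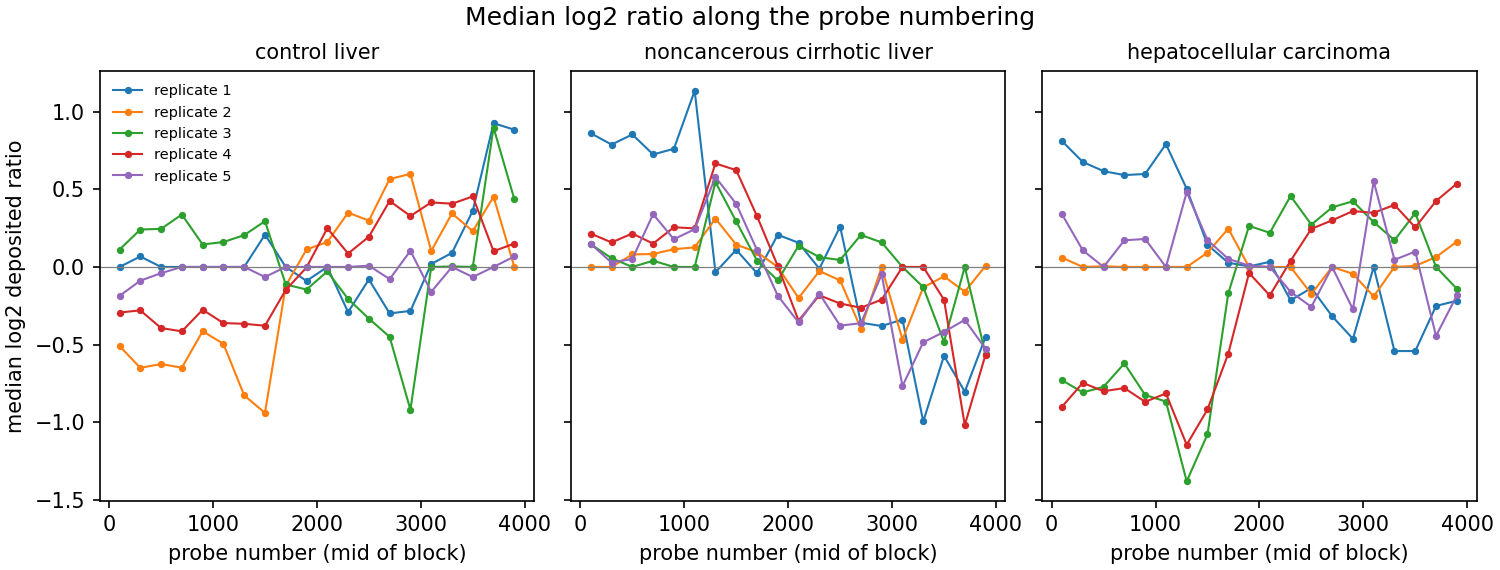
Median log2 deposited ratio (vertical axis) in blocks of 200 probe numbers (horizontal axis), one panel per group and one line per sample. Neighbouring probes moved together in each of the 15 samples, with correlations between next neighbours from 0.068 to 0.475.

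The second comparison set hepatocellular carcinoma against control liver, for the change in the tumour relative to liver of rats on the basal diet. As a group, ribosomal protein genes were higher in the tumour, with a median difference of 0.65 over 42 genes, 34 of them above 0 (camera adjusted p = 0.0016, and adjusted p = 0.684 with an estimated correlation). Their mean per sample was 0.29 ± 0.62 (SD, n = 5) in the tumour and -0.23 ± 0.27 (SD, n = 5) in control liver (exact permutation p = 0.159). Among them Rps29 differed by 1.61 (0.46 to 2.76), Rpl12 by 1.53 (-0.19 to 3.24), Rps26 by 1.37 (0.36 to 2.38) and Rps6 by 1.27 (-0.50 to 3.05; 0.56 without carcinoma 5). Rpl39 differed by -1.11 (-2.60 to 0.38; -0.39 without control 5 and -1.72 without control 2). Glycolysis genes of nonhepatic type were also higher, with a median of 0.47 over 20 genes, 16 of them above 0 (camera adjusted p = 0.0176, adjusted p = 0.684 with an estimated correlation, and exact permutation p = 0.175 for the mean per sample). Eno1, a widely expressed enolase and so by itself no sign of a nonhepatic isoform, differed by 2.43 (0.98 to 3.89). The glucose transporters Slc2a3 and Slc2a1 differed by 1.32 and 1.21 (Slc2a1 by 0.71 without carcinoma 1). The lactate transporter Slc16a3 differed by 1.14 (0.11 to 2.16), while Pfkfb3 differed by -0.47 (-0.10 without carcinoma 1 or with the running median along the probe numbering removed, and -0.82 without control 4). No member of either list passed over all probes, and adjusted over the list alone 1 glycolysis gene and 0 ribosomal protein genes passed.

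Without carcinoma 1 the adjusted p was 0.138 for ribosomal proteins and 0.168 for glycolysis, and without carcinoma 5 it was 0.0915 and 0.157. Glycolysis also missed the threshold without control 4 (0.206), control 2 (0.0912) or carcinoma 2 (0.0504), and with a floor at the 25th percentile (0.0501), while cytochrome P450 genes passed as lower in the tumour without control 2 (0.0297) or carcinoma 2 (0.0444; with an estimated correlation adjusted p = 0.788 and 0.635).

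**Figure D2:**
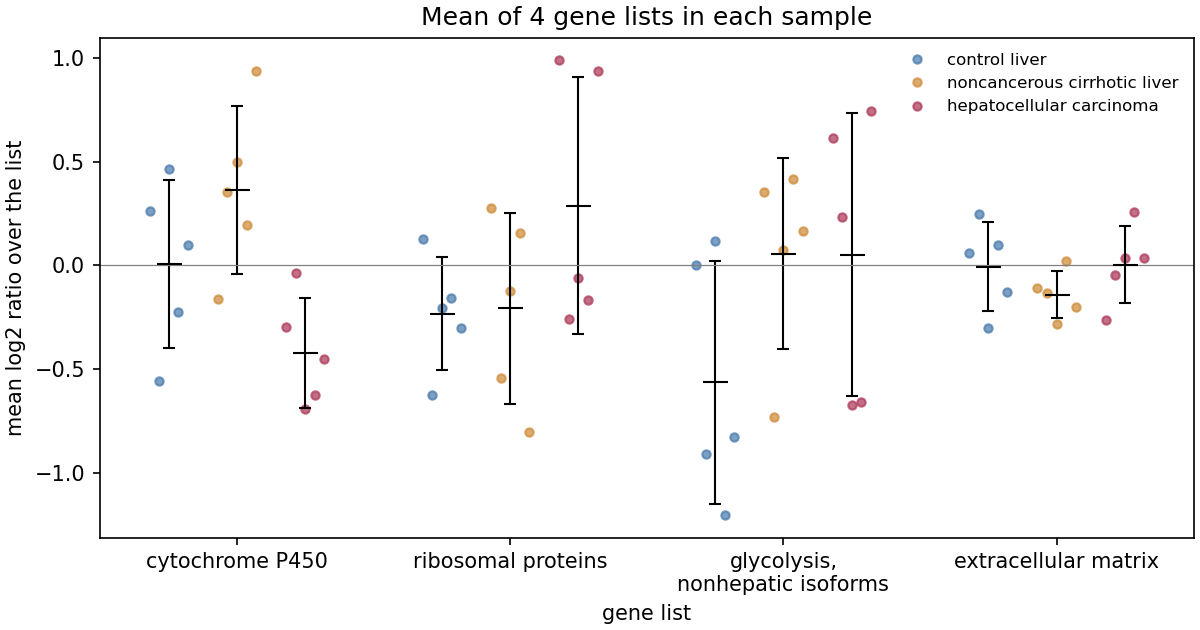
Mean normalized log2 ratio (vertical axis) of 4 gene lists (horizontal axis) in each sample, with points for samples, colours for groups and black bars for the group mean with its SD (n = 5). Cytochrome P450 averaged 0.36 in noncancerous cirrhotic liver and -0.42 in hepatocellular carcinoma. The values shown keep the trend along the probe numbering. With the running median along that numbering removed, these means were 0.07 and -0.42, and the list no longer passed camera.

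No probe passed an adjusted p of 0.05 in limma between hepatocellular carcinoma and control liver (smallest 0.459). Along the probe numbering the median difference ran from 0.15 over numbers 1000 to 1199 to -0.55 over numbers 3600 to 3799. At an unadjusted p under 0.05 there were 278 probes, 137 higher and 141 lower in the tumour, against 187.9 by chance. With each array scaled to the same median the split was 180 higher of 292, and on the values as deposited 167 of 287. With the running median along the probe numbering removed, 11 of the 16 separated genes named here remained separated. Complete separation was seen for 71 probes, 40 higher and 31 lower, against 29.8 by chance. Of 100 simulated draws of unchanged groups 19 gave as many unadjusted probes (highest 882) and 7 as many separated ones (highest 334). Among separated genes, chosen after their values were seen, those furthest above 0 were Zbtb7a (a transcriptional repressor) with a difference of 3.56 (1.29 to 5.83, adjusted p = 0.485), Fgg (the gamma chain of fibrinogen) with 2.80 (1.29 to 4.31, adjusted p = 0.459) and Plau (urokinase) with 2.65 (1.34 to 3.97). Psme2 (a proteasome activator subunit) followed with 2.21, Igfbp5 (an insulin-like growth factor binding protein) with 2.15, Slc15a2 (a peptide transporter) with 2.04, Dpp6 with 1.98 and Pspn with 1.97. Those furthest below 0 were Kcnj8 with -2.37, Cyp3a2 (a drug-metabolizing cytochrome P450 of male rat liver) with -2.34, Il1rn (the interleukin-1 receptor antagonist) with -2.26, Alas1 (which starts haem synthesis) with -2.22, Gys2 (liver glycogen synthase) with -2.06 (-1.18 without carcinoma 4), Mllt3 with -1.96, Stat6 with -1.89 and Nf1 with -1.88.

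Of the 14 fixed markers, none passed between hepatocellular carcinoma and control liver. Cyp2c11, the main male-specific cytochrome P450 of rat liver, differed by -1.09 (-2.30 to 0.13, adjusted p = 0.714) and Pemt by -0.84 (-1.78 to 0.10; -0.52 with the running median along the probe numbering removed). The tumour markers Afp, Gpc3, Gstp1 and Igf2 differed by 0.12 (-0.89 to 1.14), -0.91 (-2.92 to 1.09), 0.25 (-1.14 to 1.65) and -0.39 (-1.41 to 0.63). Leaving out 1 sample moved each of these: Afp from -0.19 (without carcinoma 3) to 0.33 (carcinoma 2), Gpc3 from -1.39 (carcinoma 5) to -0.30 (carcinoma 1), Gstp1 from -0.02 (control 4) to 0.60 (control 1) and Igf2 from -0.60 (carcinoma 2) to -0.18 (control 5). With the running median removed Afp differed by 0.22 and Gstp1 by 0.16. Preneoplastic focus and fetal liver markers as a list had a median of 0.16 over 19 genes (adjusted p = 0.678), cell cycle genes -0.19 over 29 (adjusted p = 0.494) and extracellular matrix genes 0.05 over 39 (adjusted p = 0.944).

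**Figure D3:**
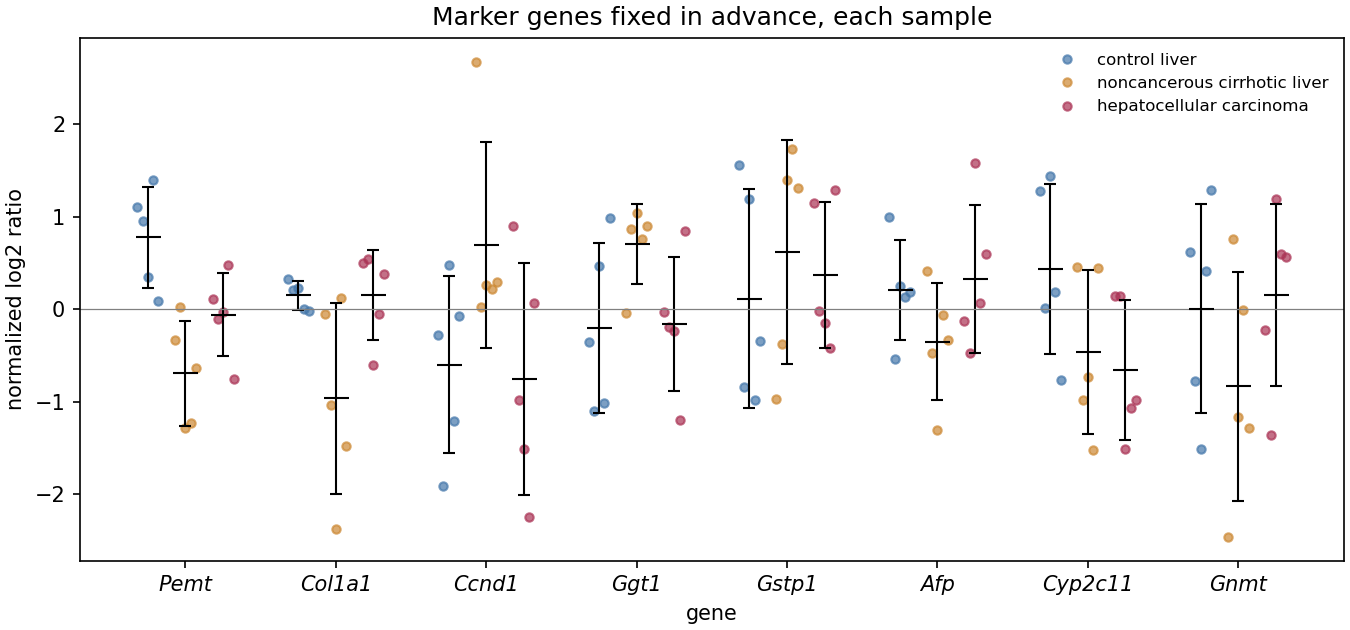
Normalized log2 ratio (vertical axis) of 8 markers fixed in advance (horizontal axis) in each sample, with points for samples, colours for groups and black bars for the group mean with its SD (n = 5). Pemt lay at -0.69 ± 0.57 in noncancerous cirrhotic liver and at 0.78 ± 0.54 in control liver. The values shown keep the trend along the probe numbering, without which Pemt did not separate these groups completely.

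The third comparison set hepatocellular carcinoma against the noncancerous cirrhotic liver around such tumours, for what was particular to the tumour among rats on the same diet. Cytochrome P450 genes were lower in the tumour as a group, with a median difference of -0.77 over 35 genes, 31 of them below 0 (camera adjusted p = 0.00122, and adjusted p = 0.684 with an estimated correlation). Their mean per sample was -0.42 ± 0.27 (SD, n = 5) in the tumour and 0.36 ± 0.40 (SD, n = 5) in cirrhotic liver (exact permutation p = 0.0159, adjusted 0.267). Cyp3a2 differed by -2.68 (-4.23 to -1.12), Cyp1b1 by -2.11 (-3.74 to -0.47), Cyp1a1, which responds to aromatic hydrocarbons, by -1.95 (-3.81 to -0.08) and Cyp2c6v1 by -1.89 (-3.65 to -0.12), while Cyp2d4 differed by 0.75 (-0.47 to 1.98; 0.41 without noncancerous 4). Ribosomal protein genes were higher in the tumour, with a median of 0.47 over 42 genes, 31 of them above 0 (camera adjusted p = 0.0176, and adjusted p = 0.684 with an estimated correlation). Their mean per sample was 0.29 ± 0.62 (SD, n = 5) in the tumour and -0.21 ± 0.46 (SD, n = 5) in cirrhotic liver (exact permutation p = 0.198). Rps15 differed by 2.48 (-0.10 to 5.06), Rpl28 by 1.75 (0.39 to 3.12) and Rpl41 by 1.40 (0.19 to 2.60), while Rpl11 differed by -0.85 (-2.16 to 0.45; -0.40 without carcinoma 3 and -1.33 without carcinoma 1). Over all probes, and over each list alone, 0 members passed.

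The median difference between hepatocellular carcinoma and noncancerous cirrhotic liver also followed the probe numbering, from -0.85 over numbers 1200 to 1399 to 0.71 over numbers 3000 to 3199. With the running median along the probe numbering removed, neither list passed between hepatocellular carcinoma and noncancerous cirrhotic liver, with an adjusted p of 0.202 for cytochrome P450 and 0.239 for ribosomal proteins. Among their genes Cyp2c6v1 then differed by -1.16, Rpl28 by 1.15 and Rpl11 by -0.56. The ribosomal protein call also ended without carcinoma 1 (0.367), carcinoma 5 (0.21) or noncancerous 5 (0.14).

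No probe passed an adjusted p of 0.05 in limma between hepatocellular carcinoma and noncancerous cirrhotic liver (smallest 0.224). At an unadjusted p under 0.05 there were 497 probes, 261 higher and 236 lower in the tumour, against 187.9 by chance. Complete separation was seen for 102 probes, 47 higher and 55 lower, against 29.8 by chance. Of 100 simulated draws of unchanged groups 1 gave as many unadjusted probes (highest 607) and 2 as many separated ones (highest 133). The draws dealt out residuals left after subtracting group means, so they hold no trend along the probe numbering that a group shared. With the running median along that numbering removed, the unadjusted count was 355. Of 100 groupings of the samples, the real one included, 6 gave at least 497. With each array scaled to the same median the split was 236 higher of 385, and on the values as deposited 219 of 373. Without noncancerous 5, 2 genes passed, both higher in the tumour: Fgg, by 4.05, and Zbtb7a, by 4.47 (adjusted p = 0.00755 for each). With noncancerous 5 they differed by 3.37 and 3.24 (adjusted p = 0.224 and 0.24), and its own log2 ratios were 1.48 and 4.41.

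Among separated genes between hepatocellular carcinoma and noncancerous cirrhotic liver, chosen after their values were seen, those furthest above 0 were Cplx1 at 3.05, Dpys (dihydropyrimidinase) at 2.93, Coro7 at 2.55, Rps15 at 2.48, Hoxc4 at 2.26, Nr0b2 (a nuclear receptor that represses bile acid synthesis) at 2.26, Gls2 (liver glutaminase) at 2.19 and Lgals3 (galectin-3) at 2.16. Those furthest below 0 were Tap1 (a peptide transporter of antigen presentation) at -3.43, Otc (the urea cycle enzyme ornithine transcarbamylase) at -3.04, Stx6 at -2.50 (-1.42 without carcinoma 5), Pgf at -2.35, Fgf5 at -2.34, Slc9a3 at -2.28, Slco1a3 at -2.28 and Psmb8 (an immunoproteasome subunit) at -2.23 (-1.26 without carcinoma 4). Among the fixed markers Ccnd1 differed by -1.45 (-2.83 to -0.06, adjusted p = 0.356), Col1a1 by 1.12 (0.01 to 2.22, adjusted p = 0.372), Igf2 by -0.93 (-1.95 to 0.08), Gnmt (glycine N-methyltransferase, which regulates the methyl donor pool) by 0.99 (-0.40 to 2.38) and Afp by 0.68 (-0.34 to 1.69). Without noncancerous 1 the difference of Ccnd1 was -0.92 and that of Gnmt 0.56, and without carcinoma 3 that of Afp was 0.36. With the running median along the probe numbering removed, 4 of the 16 separated genes remained separated. The differences were then -1.26 (-2.58 to 0.06) for Ccnd1, 0.55 (-0.72 to 1.81) for Col1a1, -0.63 (-1.54 to 0.28) for Igf2, 0.42 (-0.98 to 1.82) for Gnmt and 0.60 (-0.30 to 1.51) for Afp.

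Sets of probes shared between comparisons were empty at the adjusted threshold: 0 changed in both tissues of choline-deficient rats against control, 0 in the tumour against both other tissues, and 0 in cirrhotic liver and back again in the tumour. At an unadjusted p under 0.05, 47 probes differed from control in the same direction in both tissues, where unchanged groups simulated against the same controls gave a mean of 45.6 and up to 428, and independent lists 13.4. With the controls split between the comparisons the count was 8 or 7. That split leaves fewer control samples in each comparison, which can lower the count by itself. The tumour differed from both other tissues in the same direction for 95 probes, where the simulation gave a mean of 35.8 and up to 177, and independent lists 18.4. For 143 probes a difference between cirrhotic and control liver was followed by the opposite one between tumour and cirrhotic liver, where the simulation gave a mean of 39.4 and up to 318, and independent lists 24.1. The simulated draws hold no trend along the probe numbering that a group shared, so they may understate these counts. Across genes, which are not independent replicates, the log2 differences of both tissues from control correlated at 0.34 against 0.49 in the simulation, and their covariance was 0.21 against 0.262. With split controls the correlation was -0.11 or 0.06.

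Tumours did not differ detectably from livers in how much samples of a group varied. The median absolute deviation of a probe from the mean of the other 4 samples of its group was 0.76 ± 0.05 (SD, n = 5) in hepatocellular carcinoma, 0.72 ± 0.07 (SD, n = 5) in noncancerous cirrhotic liver and 0.77 ± 0.06 (SD, n = 5) in control liver on the log2 scale. The exact permutation p was 0.349 for the tumour against cirrhotic liver, 0.881 for the tumour against control liver and 0.262 for cirrhotic against control liver.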

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

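The outlier test was set before the data were seen, and the genes it was applied to, other than the fixed markers, were chosen after. Of 189 groups of 5 values tested, 17 held a sample far from the other 4 by Dixon's criterion, where chance gives about 1 in 20, or 9.45. By arrays, noncancerous 1 had 209 values at the lower limit against 0 to 10 in the other samples of its group, and an SD of log2 ratios of 2.11 against 0.79 to 0.98. Carcinoma 1 had 33 values at the limit against 1 to 8 in the other tumours.

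For genes, 14 of 174 groups held such a sample, given as its log2 ratio. In noncancerous 1 the outlying values were -0.0428 for Ggt1, 2.67 for Ccnd1, 3.09 for Slc9a3 and -2.46 for Cyp2c6v1. The value of Ccnd1 compares with 0.02 to 0.29 in the other 4 cirrhotic samples. In other cirrhotic samples they were 2.41 for Cd28 in noncancerous 2 and -2.88 for Got1 in noncancerous 4. In control liver they were -5.81 for Syn2, 3.17 for Mgat5 and 0.44 for Eno1 in control 4, -2.17 for Pspn in control 5 and 2.36 for Stat6 in control 3. In hepatocellular carcinoma they were 1.65 for Nr0b2 in carcinoma 2, -5.81 for Stx6 in carcinoma 5 and -5.21 for Psmb8 in carcinoma 4.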

How the results depend on the processing

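Settings with the trend along the probe numbering removed, the 10th percentile floor, values at the limit set to missing, control 1 and noncancerous 1 left out, and the exact permutation test of lists were chosen after seeing the data. The count of probes past the adjusted threshold in limma was 0 in each comparison under every setting run, except for 2 probes between carcinoma and cirrhotic liver without noncancerous 5, and the 3 shared sets stayed at 0. Leaving out 1 sample gave 0 to 0 probes in both comparisons with control liver and 0 to 2 between carcinoma and cirrhotic liver. Unadjusted counts ranged from 279 to 528 for cirrhotic against control liver, 207 to 366 for carcinoma against control liver and 335 to 671 for carcinoma against cirrhotic liver. With the stricter filter, which tested 2124 probes, the unadjusted counts were 213, 167 and 297 in that order. On ratios to the probe median that filter selects by high ratios, not brightness, and can favour probes high in a whole group. Its counts are therefore no independent check. Array quality weights gave 756 for carcinoma against cirrhotic liver. For cirrhotic against control liver, removing the trend gave 158, 149 with the shorter window, 162 with the longer one and 191 with array quality weights, all near the 187.9 of chance; the cause was not tested further. The 10th percentile floor that had been planned gave 405, 290 and 529.

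Of 2 lists shifted between carcinoma and control liver, 1 passed with a floor at the 25th percentile, and 0 with an estimated correlation, with fry or with the exact permutation test. Of 2 between carcinoma and cirrhotic liver, 0 passed with an estimated correlation, with fry, with the exact permutation test or with the trend removed at any of 3 window widths. Between cirrhotic and control liver 3 passed without control 1 and noncancerous 1, against 0, and with an estimated correlation none of these 3 did. Leaving out 1 sample gave 0 to 2 lists for cirrhotic against control liver, 0 to 2 for carcinoma against control liver and 1 to 2 for carcinoma against cirrhotic liver. The cause was not tested. The adjusted p ranged from 0.000104 to 0.00638 for cytochrome P450 between carcinoma and cirrhotic liver when 1 sample was left out, from 0.00118 to 0.367 for ribosomal proteins in that comparison, and against control liver from 4.85e-05 to 0.138 for ribosomal proteins and from 0.00133 to 0.206 for glycolysis. Scaling each array to the same median put the median of all probes at 0.107 for cirrhotic and 0.15 for carcinoma against control liver, in place of 0.0153 and 0.00294, and turned the direction of none of these lists. The spread within groups between carcinoma and control liver was -0.00505 and became 0.0084 on the values as deposited, with exact permutation p = 0.881 for both.

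The labels do not say whether samples with the same number share an animal. Same-numbered samples deviated together with a correlation over 0.1 in 1, 3 and 2 of 5 pairs (highest 0.387, noncancerous 1 and carcinoma 1), and the sample correlated best with its own number in 1 of 5 in each comparison. With the replicate block the adjusted counts stayed at 0, the unadjusted counts were 370, 274 and 506, and 0, 2 and 2 lists passed. With the block in cirrhotic and carcinoma samples alone the unadjusted count was 510. None of the 109 gene differences covered by the naming rule was past the threshold, and 48 were chosen for complete separation, so their stability was in large part settled by that choice. With 1 sample left out 39 of 1635 values changed sign, and over 16 other settings 48 of 1744.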

Other observations

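Tests of the trend along the probe numbering, of pairs of probes of the same gene, of the marker lists with the trend removed, of the marker lists by interval, of the list differences with the trend removed, of the lists by exact permutation, of the pair of control 5 and noncancerous 2, of the principal components, and of the adjusted counts over other splits were chosen after the result was seen. Leaving out control 1 and noncancerous 1 together was added after seeing the data and before its result was known. Among lists not described above, chosen after their values were seen, macrophage markers had a median difference of 0.55 between hepatocellular carcinoma and noncancerous cirrhotic liver over 14 genes, 11 of them above 0 (exact permutation p = 0.00794, camera adjusted p = 0.176). Acute phase proteins had 0.39 over 18 genes, 13 of them above 0 (exact permutation p = 0.00794, camera adjusted p = 0.369). Antigen presentation genes had -0.32 over 16 genes (exact permutation p = 0.0159), and 5 of them passed when adjusted over the list alone, in both directions: Tap1 at -3.43, Psmb8 at -2.23 and Tap2 at -1.57, and Psme2 at 2.04 and RT1-Bb at 1.59. Bile duct cell markers had -0.45 over 19 genes, 15 of them below 0 (exact permutation p = 0.0714). Of the 84 list tests by exact permutation 9 had p under 0.05, and 0 passed after adjustment (smallest 0.222). Besides these 3 and cytochrome P450, they were growth hormone axis genes (0.00794), urea cycle genes (0.0476) and lymphocyte markers (0.0397) between cirrhotic and control liver, macrophage markers between carcinoma and control liver (0.0476), and growth hormone axis genes between carcinoma and cirrhotic liver (0.0317).

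Hepatocyte plasma proteins differed by a median of 0.50 between hepatocellular carcinoma and noncancerous cirrhotic liver over 24 genes (camera adjusted p = 0.465), and conjugation and detoxification enzymes by -0.46 over 33 (adjusted p = 0.378). Methyl group and choline metabolism, the pathway the diet acts on, had a median of -0.37 over 22 genes between cirrhotic and control liver, with 4 lower and 0 higher at an unadjusted p under 0.05 (adjusted p = 0.412). Over all 3757 probes 211 were lower and 151 higher at that threshold. With the running median along the probe numbering removed, its members Pemt and Gnmt went from -1.47 to -0.68 and from -0.84 to -0.12. Red blood cell transcripts, with 4 genes, were too few to test and had a median of 0.00 between cirrhotic and control liver and -0.55 between carcinoma and control liver.

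Whether other groupings of the samples give the same counts was tested on 100 of the 126 splits of each pair of groups, the real one included. For cirrhotic against control liver 100 splits gave at least the real 0 probes past the adjusted threshold, with up to 73 in another split, 9 gave at least the real 362 unadjusted probes (highest other 678), and 100 gave at least the real 0 lists (highest other 5). For carcinoma against control liver 100 gave at least 0 probes (highest other 2), 25 at least 278 unadjusted (highest other 683) and 33 at least 2 lists (highest other 4). For carcinoma against cirrhotic liver 100 gave at least 0 probes (highest other 19), 6 at least 497 unadjusted (highest other 753) and 41 at least 2 lists (highest other 5). Where the real count is 0 every split gives at least as many by construction, so those 4 tests say nothing. For the other 5 counts, the 2 shifted lists of each comparison with the tumour included, chance was not excluded. The split that called 73 probes where the real one called 0 was the highest of those drawn. Whether it reflects a structure of the samples that does not follow the groups was not tested.

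Neighbouring probe numbers shifted together within an array. The correlation of next neighbours lay above that of shuffled orders in 15 of 15 arrays, and at a distance of 200 probes in 11, so an uneven signal along the array or the probe set may remain in the deposited ratios. A group difference in the genes of each stretch would need arrays of a group to share the profile. The correlation of block medians was 0.275 higher within groups than between them (permutation p = 0.032), between the bounds set for and against it, so this explanation stays open.

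Lists of cirrhosis and tumour markers did not shift: extracellular matrix, stellate cell and myofibroblast, and preneoplastic focus and fetal liver genes passed in none of the 3 comparisons. Probes that follow their gene poorly are a candidate explanation: over 42 pairs of probes of the same gene the median correlation over the 15 arrays was -0.027 (random pairs gave -0.014), and the differences agreed in sign in 61 of 126. With the trend removed it was 0.132, above random pairs (permutation p = 0.0186) and still low. The same limit holds for the genes named singly above. Of the 3 lists 0 passed once the trend was removed and 0 without control 1 and noncancerous 1, but a missed threshold does not exclude a hidden shift. A list of 40 random genes moved by 0.5 between carcinoma and control liver was found in 12 of 20 simulated draws. The lists here held 15, 19 and 39 genes, and neither comparison with cirrhotic liver was simulated. The preneoplastic markers of cirrhotic against control liver had a median of 0.47 (camera adjusted p = 0.494). Without both arrays it was 0.64 (adjusted p = 0.133), with a mean difference of 0.45 (95% interval -0.17 to 1.07). With the trend removed their mean difference was 0.07 (-0.36 to 0.49), in place of 0.26. In that comparison the stellate cell and myofibroblast mean was then 0.12 in place of 0.31, and the extracellular matrix mean -0.06 in place of -0.14. A shift hidden by the trend would have grown instead. The means before and after come from the same 15 arrays, so their separate intervals cannot tell whether removal changed them. That change was not tested. The 95% intervals lay within 0.5 of 0 in each comparison for extracellular matrix genes under both settings and for stellate cell and myofibroblast markers with the trend removed, but that bound was taken from the simulated lists, so both explanations stay open, as does a true lack of change.

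Ribosomal protein genes were higher in the tumour than in control liver, and cytochrome P450 genes lower in the tumour than in cirrhotic liver, by camera with a preset correlation. With an estimated correlation neither passed (adjusted p = 0.684 for each), and the exact permutation p was 0.159 and 0.0159. Removing the trend left 98.4% of the ribosomal difference from control liver (0.51 against 0.52), which argues against the trend in that comparison only. Against cirrhotic liver the ribosomal list no longer passed camera once the trend was removed. Of the cytochrome P450 difference 61.7% was left (-0.48 against -0.78), between the bounds set for it, so there the trend stays open. Leaving out carcinoma 1 moved the ribosomal difference from control liver to 0.34, a factor of 1.55, so a few arrays may carry it. No sample moved the cytochrome P450 difference by more than 1.21 times, which argues against single arrays as its source, and the tumour itself stays open for both.

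Control 5 and noncancerous 2, which carry different labels and numbers, correlated at 0.761 across probes on the deposited log2 ratios and at 0.763 with the trend removed, the highest of all pairs of arrays. The next highest pair on the deposited ratios, carcinoma 3 and carcinoma 4, stood at 0.534. For cirrhotic against control liver, limma gave 528 unadjusted probes without control 5 in place of 362 (smallest adjusted p = 0.0685). Without noncancerous 2 it gave 351 (smallest adjusted p = 0.305). Of the variance between samples, the first principal component held 23.9%, of which 9.41% lay between groups (permutation p = 0.528), and the second held 17.6%, of which 55.2% lay between groups (permutation p = 0.0129). Scores on the second were lowest in carcinoma 3 (-45.5), carcinoma 4 (-41.2), control 2 (-30.2) and control 4 (-30.2). In these arrays the variance of the running median along the probe numbering was 29.0%, 33.2%, 17.9% and 19.1% of that of the log2 ratios. For the latter variance alone the lowest ratios were raised to a floor, so this figure is no exact share. The highest scores were 42.1 in noncancerous 5, 40.1 in noncancerous 2, 34.3 in noncancerous 4 and 23.2 in control 5. For these arrays the figure was 16.03%, 4.91%, 19.56% and 1.801%, in that order. The trend may contribute to the share between groups, which was not tested.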
